A study of Homo sapiens with 8 samples.

How the data were processed

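RNA was measured in 8 libraries of human cancer-associated fibroblasts, 2 for each of 4 substrates. Per the labels' protocols, RNA was extracted with Trizol, cleaned on columns and made into libraries with a stranded Illumina TruSeq kit after capture on oligo-dT beads. Per the submitters' processing notes, bcl2fastq 2.20, HISAT2 and HTSeq were used with the genome build GRCh38 (hg38); the versions of HISAT2 and HTSeq, the annotation release and the strand setting of the counting are not given in the sources used here. The deposited values are raw counts per Ensembl gene, whole numbers with no normalization by the authors, in 1 table per library.

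Each table held 60623 genes and 5 entries that name no gene (no feature, ambiguous, low alignment quality, not aligned, not uniquely aligned). The latter stayed out of library sizes and tests. They made up 25.5% to 50.5% of the records of a library, and ambiguous records made up 3.02% to 5.33%. Gene counts per library ranged from 40948362 to 58732594. Mitochondrially encoded genes took 4.03% to 5.55% of them. Names were found for 60604 gene IDs; coordinates, exon lengths, GC content and overlaps of gene models come from GENCODE 29 on GRCh38, which holds 58516 of the IDs and may not be the authors' release. Because the strand setting is not given, genes with an overlapping or antisense partner are uncertain. Genes that could point to a person were left out of what is reported.

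Groups were taken from the labels. Genes were kept by edgeR's filterByExpr on the groups (17128 genes), scaled by TMM and tested with edgeR 4.0.16 (limma 3.58.1, R 4.3.3): estimateDisp, glmQLFit with robust shrinkage and glmQLFTest, 1 mean per substrate, all 8 libraries in the fit. The fit had 4 residual degrees of freedom and a biological coefficient of variation of 10.4%. Fold changes are on the log2 scale with SE, computed as the absolute log2 fold change over the square root of F; p-values were adjusted by Benjamini-Hochberg over all genes of a comparison and called under 0.05. Levels are CPM (counts scaled to a common library size) on TMM-scaled library sizes, given as mean and SD of 2 libraries. The 95% interval given for COL1A1 used the prior degrees of freedom of the first gene in the fit, so its width is approximate. The slope over the gels used the centred log10 of the modulus. The 27 gene lists were tested by camera with a preset correlation of 0.01 and again with an estimated one, adjusted over the lists of a comparison, for lists with at least 5 tested genes. The estimated correlation rests on the 4 residual degrees of freedom, and its power to call a list was not tested. A missing call with it therefore does not count against a list. The preset correlation of 0.01 treats list members as varying almost independently between libraries. With it some lists, such as the inflammatory one, turned direction with the library left out. A call with the preset correlation alone therefore does not settle that a list moved. Another list test, fry, was run beside camera and is not reported here.

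The text names genes by a rule fixed before the data were examined: for 40 against 1 kPa and plastic against 40 kPa up to 10 rises and 10 falls with the largest fold among called genes with a mean log2 CPM of at least 2, both libraries of a group above both of the other, and a proper symbol; up to 5 and 5 for the other comparisons; up to 4 members of each list with the smallest p; and a panel of 26 genes. Some genes that this rule selects are not reported here. The lists, the tests and the other settings to be tried were fixed at the same time. The lists cover YAP/TAZ targets, actin and contractile genes, focal adhesion, collagens, matrix glycoproteins, proteases, inflammatory cytokines, TGF-beta signalling, growth factors, G2/M, S phase, cholesterol and fatty acid synthesis, glycolysis, ATF4 targets, p53 targets, immediate early, interferon-stimulated, mitochondrial, histone, ribosomal and lysosome genes, and markers of fibroblasts, epithelium, endothelium, leukocytes and pericytes.

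The other settings were RLE scaling, library size alone, no filter, a filter of 50 counts in 2 libraries, DESeq2 1.42.0, the replicate number as a block, a fit of only the groups compared, shrinkage without the robust option, an estimated correlation for camera, and leaving out each library. Corrections along exon length, along GC content and along both were added after the data had been seen. Each removes a smooth trend per library through an offset. The trend is taken against the mean of all libraries, so a trend that differs between substrates is removed as well. A call lost or gained under a correction can therefore reflect either a bias or a removed difference between substrates. On counts simulated from the means of these libraries, with 200 changed genes among 17128 for the 40 against 1 kPa comparison, edgeR recovered 62.7% of genes changed 1.5-fold, 89.6% of those changed 2-fold and 100% of those changed 4-fold, with 11 false calls. For plastic against 40 kPa the shares were 58.2%, 94% and 100%, with 15 false calls. The changed genes were drawn from the better expressed ones, so the shares recovered do not cover genes with the lowest counts. These simulations share 1 dispersion per gene over all groups and so do not carry the wider spread of the plastic pair.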

Results

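Human cancer-associated fibroblasts (CAF05, primary cells from a colorectal tumour) were cultured for 48 h on polyacrylamide gels with an elastic modulus of 1, 10 or 40 kPa, or on a plastic dish with a modulus of 3.4 GPa. The gels carried fibronectin; the labels do not name a coating for the dish. Polyadenylated RNA was sequenced in 2 libraries per substrate, 8 in all. The libraries held 58732594 and 47117615 gene counts on the 1 kPa gel, 40948362 and 51218304 on 10 kPa, 53344427 and 44602509 on 40 kPa, and 54890173 and 48403947 on plastic. Nothing in the labels says whether replicates were separate cultures, so p-values measure only the spread between these libraries. On log counts, the first principal component held 47.1% of the variance and placed the libraries in the order 1 kPa, 10 kPa, then 40 kPa with plastic. The second held 14.1% and set plastic replicate 2 (score 40.5) apart from plastic replicate 1 (score -6.65). The third held 9.3% and gave 10 kPa replicate 2 a score of 31.4 and 10 kPa replicate 1 a score of -8.04. The scores of 40 kPa replicate 2 and replicate 1 on it were 16.05 and -11.8.

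The cultures expressed fibroblast genes throughout. Of 20 fibroblast markers fixed beforehand, 19 had a mean of at least 10 CPM. Only 2 of 25 epithelial and carcinoma markers, 3 of 15 endothelial markers, 5 of 15 pericyte and smooth muscle markers and 0 of 19 leukocyte markers reached that level. The fibroblast markers went both ways. VIM (3511 and 4952 CPM on the 1 and 40 kPa gels) and CAV1 (696 and 1013 CPM), picked after their values were seen, had higher means on 40 kPa. PDGFRB, a receptor for platelet-derived growth factor, fell from 135 CPM on the 1 kPa gel to 80.05 CPM on the 40 kPa gel. FAP, a surface protease of activated fibroblasts, fell from 53.01 to 31.97 CPM and stood at 52.8 CPM on plastic. PDGFRA, the sister receptor of PDGFRB, had a log2 fold change of -0.61 and the transcription factor gene TCF21 -0.55. Both calls were lost without 1 kPa replicate 1 (log2 fold changes -0.54 and -0.50) or 40 kPa replicate 1 (-0.57 and -0.53). ACTA2, which encodes smooth muscle actin, was low on every substrate, at 11.7 ± 0.117 CPM on 1 kPa and 12.8 ± 0.592 CPM on plastic (SD, n = 2).

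The comparison of the 40 kPa with the 1 kPa gel asks how these cells differ between gels that the labels set apart by modulus only. The labels do not name separate cultures, so differences between cultures cannot be told apart from those of modulus. All libraries came from CAF05, so other donors were not covered. Of 22 targets of the mechanosensitive coactivators YAP and TAZ, 18 rose and 1 fell on the stiffer gel, and the list was called higher only with a preset correlation (adjusted p = 0.222 with an estimated correlation). CCN1, a secreted matricellular protein (chromosome 1, 85580761 to 85583962, GRCh38), rose from 237 ± 20.3 to 660 ± 79.3 CPM, and CCN2, its relative, rose from 128 ± 6.24 to 317 ± 6.75 CPM (SD, n = 2). The growth factors AREG and NRG1, both ligands of the ErbB receptor family, fell. AREG (chromosome 4, 74445134 to 74455009) went from 82.6 ± 0.143 to 4.53 ± 1.98 CPM, and NRG1 from 70.4 ± 0.438 to 9.69 ± 0.637 CPM. In edgeR's quasi-likelihood test, 1093 genes were higher and 1654 lower of 17128 tested, with 218 and 749 of them changed at least 2-fold.

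**Figure D1:**
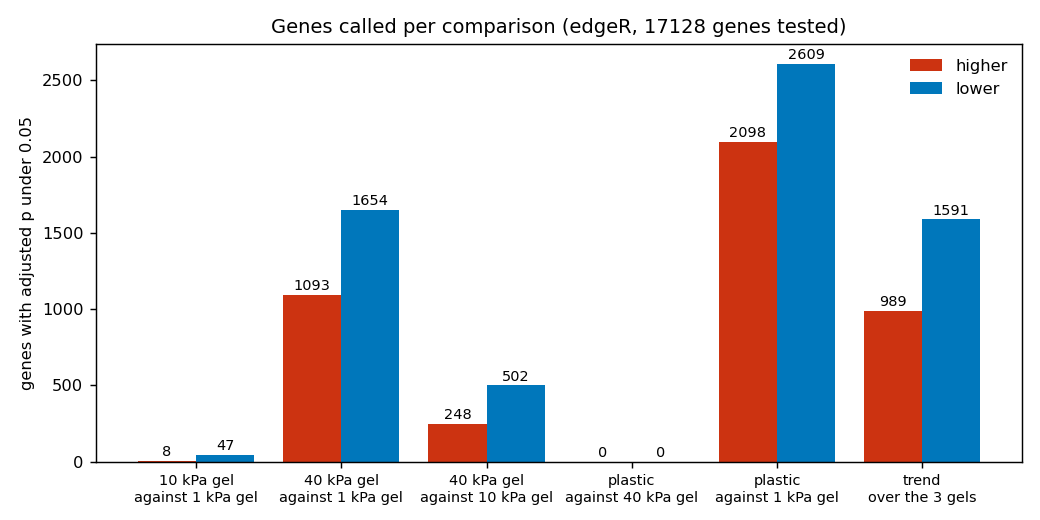
Bars give the number of genes with an adjusted p under 0.05 in each comparison, higher (red) and lower (blue), from edgeR over 17128 genes and 2 libraries per group. Plastic against the 40 kPa gel gave 0 calls, and plastic against the 1 kPa gel gave 2098 higher and 2609 lower.

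Of the 10 largest rises by the fixed rule, FGF5, a fibroblast growth factor, had a log2 fold change of 1.70 (SE 0.12, adjusted p = 1.91e-07), and HAS2, a hyaluronan synthase, 1.71 (SE 0.14, adjusted p = 1.11e-06). PTX3, a secreted pentraxin, had 1.89, KRTAP1-5 1.97, KRTAP2-3 1.85, KRT34 1.74, ATP8B1 1.70 and SLIT2, an axon guidance ligand, 1.65. CLDN1, a tight junction protein, had 2.31 with an SE of 0.53 (adjusted p = 0.0396), and the call was lost without 1 kPa replicate 1 (adjusted p = 0.296), 1 kPa replicate 2 (0.216), plastic replicate 1 (0.102) or plastic replicate 2 (0.101), with RLE scaling (0.0502) and with no filter on low counts (0.168). RNA5-8SN3, a ribosomal RNA gene with near-identical copies and so an uncertain count, had 1.66. Its call was lost without 1 kPa replicate 1 (log2 fold change 1.26), 40 kPa replicate 2 (1.03), plastic replicate 1 (1.67) or plastic replicate 2 (1.67). A fit of only the 2 groups compared ended the calls of PTX3 (adjusted p = 0.0741), CLDN1 (0.163) and RNA5-8SN3 (0.224). Corrections along gene properties, chosen after the data were seen, ended the call of CLDN1 (0.0522 with exon length, 0.0603 with GC content and 0.0660 with both) and, with exon length, that of RNA5-8SN3 (0.0550).

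The largest falls exceeded the largest rises in size. C11orf96 (chromosome 11, 43942505 to 43944338) went from 28.4 ± 3.06 to 0.458 ± 0.377 CPM, a log2 fold change of -6.00 (SE 0.34). PDK4, a kinase that restrains pyruvate oxidation, went from 380 ± 24.3 to 30.4 ± 12.6 CPM. PTGS2, the inducible cyclooxygenase, fell by 3.34 on the log2 scale, and the cytokine IL24 fell by 3.65. BMF, which promotes apoptosis, fell by 4.07, CHI3L1 by 3.80, the xenobiotic enzyme CYP1A1 by 3.36, the serine protease HTRA3 by 3.13 and AKR1B10 by 2.93.

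**Figure D2:**
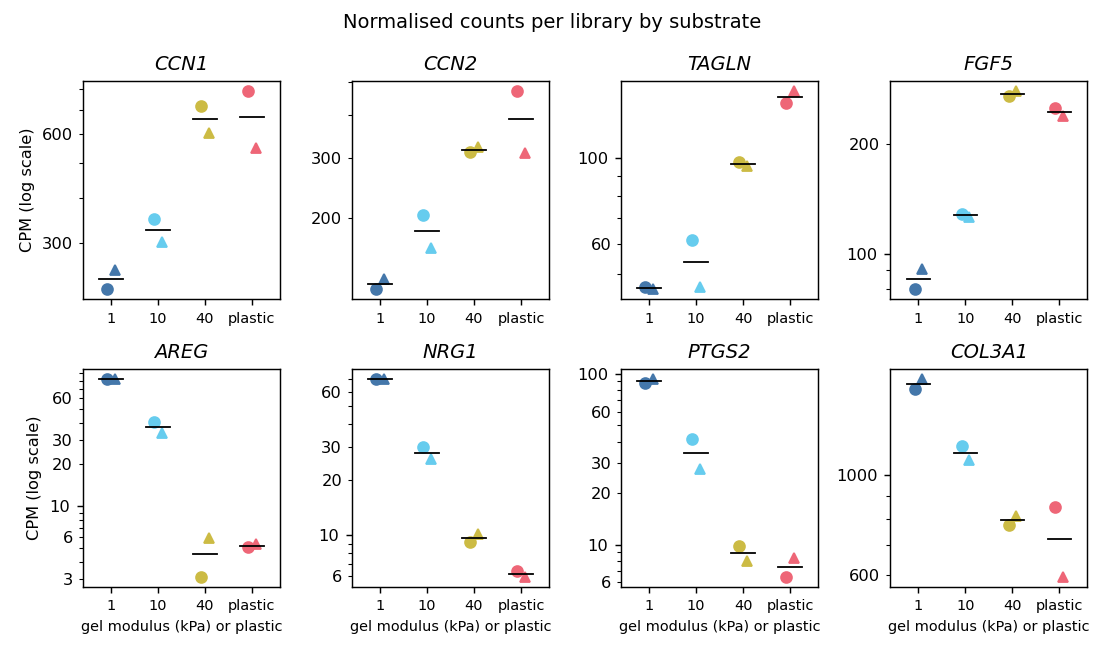
Each panel plots 1 gene as CPM on a log axis against the substrate, with replicate 1 as a circle, replicate 2 as a triangle and the mean of 2 libraries as a line. CCN1 rises from 237 to 660 CPM and AREG falls from 82.6 to 4.53 CPM between the 1 kPa and 40 kPa gels.

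Adjusted over the list alone, 19 of the 22 YAP/TAZ targets rose and 1 fell. The number that rose was 10 without 1 kPa replicate 1, 11 without 1 kPa replicate 2 and 12 without 40 kPa replicate 1, with a list median of 0.60 in the last. CRIM1 had a log2 fold change of 1.24 (SE 0.15), AMOTL2 1.25 and CCDC80 0.93. Camera called the list higher with a preset correlation (adjusted p = 1.85e-14), and not with an estimated one (adjusted p = 0.222 with an estimated correlation). The estimated version called 0 lists in every comparison, so it cannot tell lists that moved from lists that did not. ANKRD1, a nuclear ankyrin protein of the same list, had 1.36, and its call was lost without plastic replicate 1 (adjusted p = 0.0730) or plastic replicate 2 (0.0728) and in a fit of only the 2 groups compared (0.161). Of 30 actin cytoskeleton and contractile genes, 16 rose and 0 fell (21 and 0 adjusted over the list alone), among them TAGLN with 1.06, TPM1 with 0.95, CNN2 with 0.85 and CNN3 with 0.66. That list was called higher too (adjusted p = 4.82e-09), but not with an estimated correlation (adjusted p = 0.222). The number that rose in it was 5 without 1 kPa replicate 1, 8 without 1 kPa replicate 2, 10 without 10 kPa replicate 1, 10 kPa replicate 2 or 40 kPa replicate 2, and 7 without 40 kPa replicate 1. ACTA2 had a log2 fold change of -0.13 (SE 0.15, adjusted p = 0.615). CNN1 was near 1 CPM, and its rise of 1.39 was not called without 1 kPa replicate 1 (adjusted p = 0.0908), 1 kPa replicate 2 (0.0694) or 40 kPa replicate 1 (0.126).

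Matrix genes went both ways. Of 32 collagens and collagen-crosslinking enzymes, 2 rose and 7 fell (3 and 9 adjusted over the list alone). COL3A1, the chain of type III collagen, fell from 1599 ± 61.7 to 794 ± 23.8 CPM, and COL7A1, COL5A3 and COL18A1 fell by 0.91, 1.12 and 0.78 on the log2 scale. COL1A1 stood at 2903 ± 71.1 and 2870 ± 249 CPM (log2 fold change -0.02, 95% interval -0.39 to 0.35), and COL1A2 had -0.16 (adjusted p = 0.542, but called at 0.0296 in a fit of only the 2 groups compared, 0.0392 without plastic replicate 1 and 0.0461 without plastic replicate 2). LOX, which crosslinks collagen, had 0.58, a call lost without 1 kPa replicate 2 (adjusted p = 0.0798) or 40 kPa replicate 1 (0.0753). The collagen list itself was not called (adjusted p = 0.182), but it was called lower without plastic replicate 1 (0.0202; 6 rose and 13 fell) or plastic replicate 2 (0.0210; 6 and 14). Neither call held with an estimated correlation (adjusted p = 0.578 and 0.573). The falls in it were 4 without either 1 kPa or either 40 kPa library. Of 35 matrix glycoproteins and proteoglycans, 3 rose and 13 fell (3 and 17 adjusted over the list alone), with TNXB falling by 1.45 and FBLN2 by 0.84. FN1, fibronectin, had 0.32 (adjusted p = 0.199), and POSTN -0.37 (adjusted p = 0.0662); both were called in a fit of only the 2 groups compared (0.000305 and 0.00136), without plastic replicate 1 (0.00182 and 0.00737) or plastic replicate 2 (0.00171 and 0.00882). POSTN was also called with library sizes alone (0.0435), with GC correction (0.0119) and with correction of GC and exon length (0.00656). The list was called lower with a preset correlation (adjusted p = 0.0207), not with an estimated one (adjusted p = 0.625 with an estimated correlation), nor with the preset one without 40 kPa replicate 2 (0.0630). The falls in it were 7 without 1 kPa replicate 1, 8 without 1 kPa replicate 2 and 6 without 40 kPa replicate 1.

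Of 27 matrix proteases and their inhibitors, 1 rose and 15 fell (2 and 16 adjusted over the list alone). SERPINE2 fell by 1.09 on the log2 scale, ADAMTS5, an aggrecanase, by 1.53 and MMP11 by 2.57 from a low level. MMP1, an interstitial collagenase, had a log2 fold change of -1.45, and the call was lost without plastic replicate 1 (adjusted p = 0.0702) or plastic replicate 2 (0.0711) and in a fit of only the 2 groups compared (0.145). MMP3 had -0.11 (adjusted p = 0.686). Camera called the list lower (adjusted p = 8.65e-07), but not with an estimated correlation (adjusted p = 0.222). Among 29 focal adhesion and integrin genes, 6 rose and 4 fell (6 and 5 adjusted over the list alone), and the integrin chains ITGA8, ITGA10 and ITGA11 fell by 2.70, 1.14 and 1.89 on the log2 scale. ITGA2 had -0.61, a call lost without 1 kPa replicate 1 (adjusted p = 0.0769) or 40 kPa replicate 1 (0.101). The list was not called (adjusted p = 0.879; median up, mean and test down). The rises in it were 0 without 1 kPa replicate 1 or 40 kPa replicate 2, 1 without 1 kPa replicate 2, 2 without 40 kPa replicate 1, 3 without 10 kPa replicate 1 or 10 kPa replicate 2, and 13 without plastic replicate 1 or plastic replicate 2.

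Secreted signals split by gene. Of 34 growth factors, 13 rose and 10 fell (16 and 10 adjusted over the list alone), and the list was not called (adjusted p = 0.820; median up, mean and test down). The rises in it were 7 without 1 kPa replicate 1 or 40 kPa replicate 1 and 8 without 40 kPa replicate 2. STC1, a secreted glycoprotein hormone, fell from 1130 ± 155 to 225 ± 8.65 CPM. In the TGF-beta, activin and BMP list, 6 of 36 rose and 17 fell (6 and 18 adjusted over the list alone). INHBA, the activin A chain, rose by 1.01 and FST, an activin antagonist, by 1.22, whereas BAMBI fell by 1.63 and TGFB1 by 0.79. This list was called lower (adjusted p = 0.00313), and not with an estimated correlation (adjusted p = 0.625). The falls in it were 10 without 40 kPa replicate 1.

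Of 30 inflammatory cytokines and NF-kB targets, 1 rose and 6 fell (1 and 6 adjusted over the list alone), the median of 0.45 and the mean were up and the test pointed down (adjusted p = 0.182). Single libraries turned this: without 40 kPa replicate 1 the median was -0.57, 0 rose and 7 fell and the list was called lower (adjusted p = 8.50e-09), and without 40 kPa replicate 2, 14 rose and 4 fell and it was called higher (adjusted p = 6.47e-06). Neither call held with an estimated correlation (adjusted p = 0.416 and 0.585). IL33 fell by 1.16. CXCL8, a neutrophil chemokine, had a log2 fold change of 2.22 with an SE of 1.22 (adjusted p = 0.332), with 224 and 24.2 CPM in its 40 kPa libraries; it was called without the robust option (0.0287). IL6 had 1.72 (adjusted p = 0.411), with 23.8 and 2.54 CPM. Without 40 kPa replicate 2 both were called, CXCL8 with 3.06 (adjusted p = 0.00771) and IL6 with 2.56 (8.41e-05). CXCL12 was the gene that rose, with 0.52, and its call was lost without 1 kPa replicate 1 (adjusted p = 0.349), 40 kPa replicate 1 (0.196) or 40 kPa replicate 2 (0.0935), or with library sizes alone (0.0598).

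**Figure D3:**
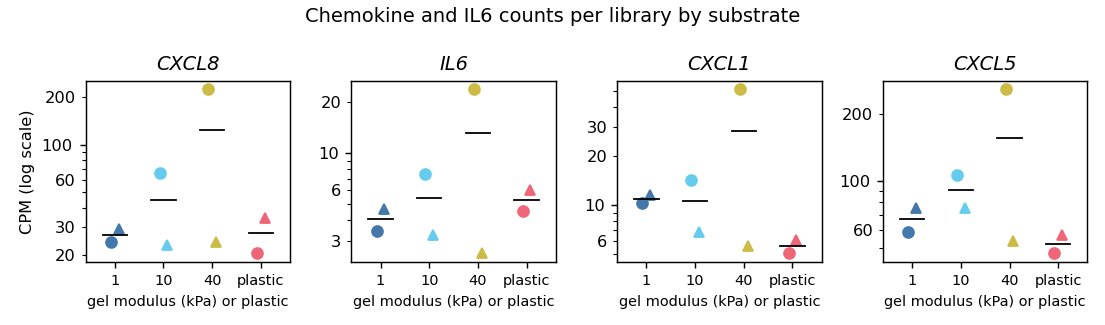
Each panel plots 1 gene as CPM on a log axis against the substrate, with replicate 1 as a circle, replicate 2 as a triangle and the mean of 2 libraries as a line. In 40 kPa replicate 1 CXCL8 stands at 224 CPM and in 40 kPa replicate 2 at 24.2 CPM.

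Of 30 G2/M and mitosis genes, 13 rose and 0 fell (21 and 0 adjusted over the list alone), among them ANLN with 0.75 and KIF23 with 0.63. MKI67 had 0.62, a call lost without 1 kPa replicate 1 (adjusted p = 0.0618) or 40 kPa replicate 1 (0.0568). Of 34 S phase genes, 13 rose and 0 fell (22 and 0 adjusted over the list alone), and RRM2, a ribonucleotide reductase subunit, had 0.61, a call lost without 40 kPa replicate 1 (adjusted p = 0.0570). TYMS, thymidylate synthase, had 0.51 and CCNE2, a cyclin, 0.80; both calls were lost without 1 kPa replicate 2 (adjusted p = 0.0921 and 0.0718) or 40 kPa replicate 1 (0.0960 and 0.118). Both lists were called higher (adjusted p = 1.98e-08 and 1.90e-08), and neither with an estimated correlation (adjusted p = 0.457 for each). Without 40 kPa replicate 1, 3 G2/M and 0 S phase genes rose in edgeR's test; the numbers were 2 and 4 without 1 kPa replicate 1, 5 and 1 without 1 kPa replicate 2, 3 and 8 without 40 kPa replicate 2, 8 and 8 without 10 kPa replicate 1 or 10 kPa replicate 2, and 26 and 30 without plastic replicate 1 or plastic replicate 2. Of 24 immediate early genes, 4 rose and 13 fell (4 and 13 adjusted over the list alone). NR4A2 fell by 2.60, FOS by 2.59 and FOSB by 1.91, while the phosphatase gene DUSP5 rose by 1.19. Of 26 lysosome and autophagy genes, 0 rose and 15 fell (0 and 16 adjusted over the list alone), including the autophagy receptor SQSTM1 by 1.34, ULK1 by 1.22, CTSD by 0.97 and WIPI1 by 0.74. These lists were called lower (adjusted p = 0.00052 and 3.96e-08), but not with an estimated correlation (adjusted p = 0.625 and 0.222). The falls in the immediate early list were 8 without 1 kPa replicate 2, 40 kPa replicate 1 or 40 kPa replicate 2. Those in the lysosome list were 7 without 1 kPa replicate 2 and 4 without 40 kPa replicate 1.

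**Figure D4:**
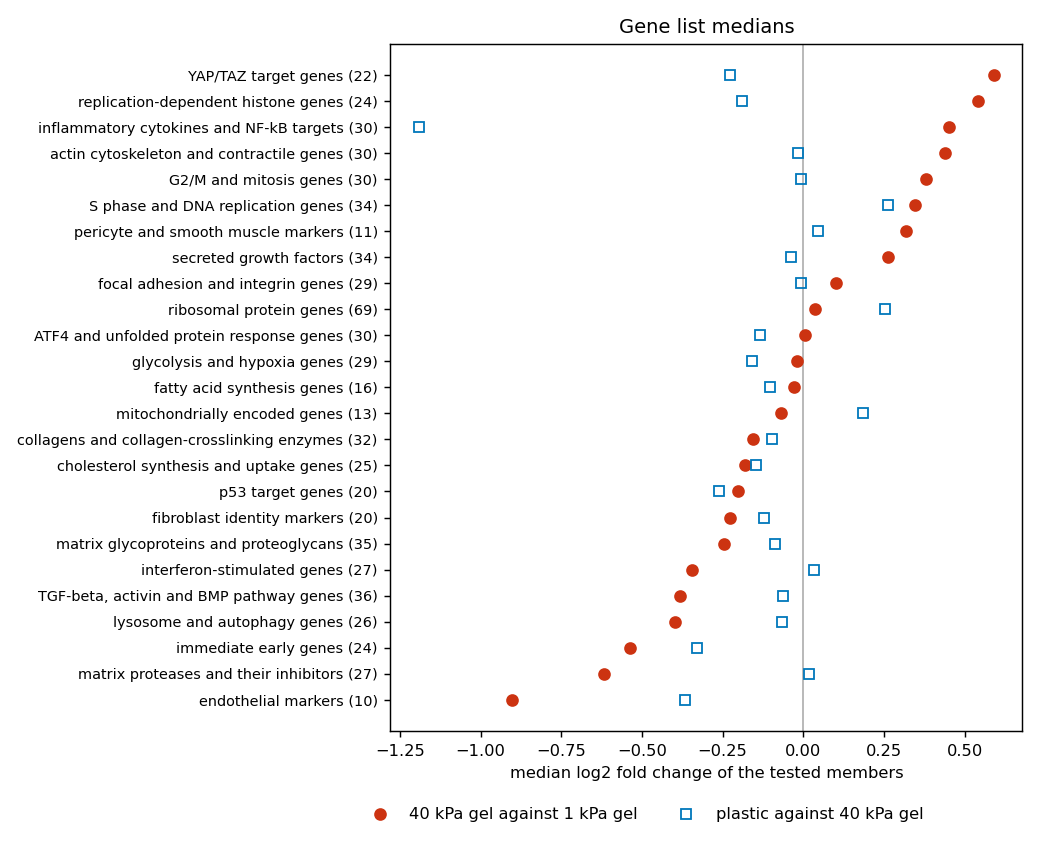
Points give the median log2 fold change of the tested members (number in brackets) of each list with at least 10 of them, for the 40 kPa against the 1 kPa gel (filled circles) and plastic against the 40 kPa gel (open squares). The YAP/TAZ targets have a median of 0.59 in the former and -0.23 in the latter.

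The count of calls for the 40 kPa against the 1 kPa gel moved with the libraries used. It was 1327 without 1 kPa replicate 1, 1401 without 1 kPa replicate 2, 1241 without 40 kPa replicate 1 and 1603 without 40 kPa replicate 2, and rose to 5732 without plastic replicate 1 and 5745 without plastic replicate 2. The plastic pair adds to the shared estimate of the spread although plastic is not in this comparison.

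The 10 kPa gel was set against the 1 kPa gel to ask where within the gel range the change begins. The genes that fell most were among those lowest on 40 kPa. C11orf96 went from 28.4 to 7.23 CPM, PTGS2 from 91.0 to 34.5 CPM, NRG1 from 70.4 to 28.0 CPM and HTRA3 from 28.4 to 11.4 CPM, and AKR1B10 had a log2 fold change of -1.27. GAS6-DT, SLC8A1, CLDN11, OGFRL1 and CDC42EP3 had the largest rises, between 0.60 and 0.83 on the log2 scale. edgeR called 8 genes higher and 47 lower, 21 of the latter at least 2-fold. CCN1 had 0.46 (adjusted p = 0.336) and CCN2 0.52 (adjusted p = 0.271). Both were called without plastic replicate 1 (adjusted p = 0.0173 and 0.00406) or plastic replicate 2 (0.0157 and 0.00609) and in a fit of only the 2 groups compared (0.000762 and 0.00923), and CCN2 with no filter on low counts (0.0281). By edgeR 0 of 22 YAP/TAZ targets rose or fell, also adjusted over the list alone, and 5 rose and 2 fell without plastic replicate 1 or plastic replicate 2. IL24 fell by 1.18 on the log2 scale, AREG by 1.15, ITGA8 by 1.16, TNXB by 0.98, FOS by 1.10, FOSB by 1.27 and NR4A2 by 0.79, and FGF5 rose by 0.58. Camera called the YAP/TAZ list higher (adjusted p = 0.000485) and the lysosome and autophagy list lower (adjusted p = 9.27e-07), and neither with an estimated correlation (adjusted p = 0.505 and 0.448).

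The number of calls was 10 without 1 kPa replicate 1, 8 without 1 kPa replicate 2, 5 without 10 kPa replicate 1 and 0 without 10 kPa replicate 2, and 1138 without plastic replicate 1 and 1142 without plastic replicate 2. With library sizes alone as the scaling it was 0 higher and 17 lower. The 10 kPa libraries differed from each other along exon length (Spearman rho 0.436 across 9133 genes of at least 10 CPM, which are not independent). With correction along exon length, chosen after the data were seen, the number of calls was 76. With the replicate number as a block the calls of GAS6-DT (adjusted p = 0.0520), CDC42EP3 (0.0520), NR4A2 (0.0520), SLC8A1 (0.0560), FGF5 (0.0634) and OGFRL1 (0.0714) were lost. These 6, CLDN11, AKR1B10 and TNXB also lost theirs with library sizes alone (0.0598 to 0.0841) and with a filter of 50 counts (0.0538 to 0.0694). C11orf96 was not called by DESeq2 (0.0845), nor PTGS2 in a fit of only the 2 groups compared (0.107). GC correction, chosen after the data were seen, ended the calls of FGF5 (0.0563), SLC8A1 (0.0803) and OGFRL1 (0.0822). No gene named for this comparison kept its call without 10 kPa replicate 2, where the adjusted p was 0.0600 for NRG1, 0.124 for IL24, PTGS2 and TNXB, 0.170 for C11orf96, 0.398 for HTRA3 and FOS, and 0.418 or more for the rest. Without 10 kPa replicate 1 the calls of NRG1, C11orf96, PTGS2, HTRA3 and IL24 stood and the others were lost (AREG 0.165, ITGA8 0.165, FOS 0.170, GAS6-DT 0.186, FOSB 0.235, AKR1B10 0.261, CDC42EP3 0.261, NR4A2 0.342, TNXB 0.372, FGF5 0.372, CLDN11 0.402, SLC8A1 0.426, OGFRL1 0.427). Without 1 kPa replicate 1 or 1 kPa replicate 2 the calls were lost for AREG (0.0844 and 0.0793), FOS (0.0972 and 0.118), NR4A2 (0.418 and 0.235), TNXB (0.0703 and 0.267), AKR1B10 (0.409 and 0.0893), FGF5 (0.743 and 0.267) and all 5 largest rises (0.267 or more). ITGA8 lost its call without 1 kPa replicate 1 (0.200), and FOSB (0.270) and HTRA3 (0.0793) without 1 kPa replicate 2. FGF5 (0.0767 and 0.0878) and the 5 largest rises (0.0546 to 0.0807) also lost theirs without 40 kPa replicate 1 or 40 kPa replicate 2. Without plastic replicate 1 or plastic replicate 2, C11orf96 (0.0662 and 0.0671), PTGS2 (0.0502 and 0.0516) and AREG (0.102 and 0.106) lost theirs.

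The 40 kPa gel was then compared with the 10 kPa gel. Among the YAP/TAZ and contractile genes that rose, CCN1 did so by a log2 fold change of 1.02, AMOTL2 by 1.05, TAGLN by 0.84, CCN2 by 0.79 and ANKRD1 by 0.79, and 10 of 22 YAP/TAZ targets rose and 0 fell (17 and 0 adjusted over the list alone). Of 30 actin and contractile genes 4 rose and 0 fell (16 and 0 adjusted over the list alone). KRTAP2-3, PTX3, CD274 (the PD-L1 immune checkpoint ligand), NUAK2 and KRTAP1-5 had the largest rises, from 1.23 to 1.45. C11orf96, AREG, BMF, PDK4 and CHI3L1 had the largest falls, with log2 fold changes of -4.02, -3.04, -2.95, -2.75 and -2.47. edgeR called 248 genes higher and 502 lower, 39 and 254 at least 2-fold. Camera called the YAP/TAZ and the actin and contractile lists higher (adjusted p = 1.07e-17 and 8.12e-12), but neither with an estimated correlation (adjusted p = 0.222 for each). The rises in these lists were 1 and 1 without 10 kPa replicate 2, 3 and 1 without 40 kPa replicate 1, 5 and 2 without 10 kPa replicate 1, 6 and 1 without 40 kPa replicate 2, and 17 and 21 without plastic replicate 1 or plastic replicate 2. The count was 242 without 10 kPa replicate 1, 290 without 10 kPa replicate 2, 197 without 40 kPa replicate 1, 2637 without plastic replicate 1 and 2645 without plastic replicate 2. Without 10 kPa replicate 2 the call of CCN1 was lost (adjusted p = 0.0562), as was that of NUAK2 (0.0630, and 0.0601 without 40 kPa replicate 1), and without plastic replicate 1 or plastic replicate 2 those of PTX3 (0.0906 and 0.0889) and CHI3L1 (0.0654 and 0.0661). The call of CCN2 was lost without 10 kPa replicate 2 (log2 fold change 0.63), 40 kPa replicate 1 (0.81) or 40 kPa replicate 2 (0.76). ANKRD1 lost its call without 10 kPa replicate 1 (log2 fold change 0.83), 10 kPa replicate 2 (0.76), 40 kPa replicate 2 (0.45), plastic replicate 1 (0.79) or plastic replicate 2 (0.79). A fit of only the 2 groups compared ended the calls of PDK4 (adjusted p = 0.108), CHI3L1 (0.164), PTX3 (0.208) and ANKRD1 (0.234). That of ANKRD1 was also lost with library sizes alone (0.0685), a filter of 50 counts (0.0543), DESeq2 (0.148), GC correction (0.0697) and correction of GC and exon length (0.123).

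Across the 3 gels, a slope per 10-fold of modulus was called higher for 989 genes and lower for 1591. The steepest were the genes that led the 40 kPa against 1 kPa comparison, with slopes of 1.18 for KRTAP1-5, 1.11 for PTX3, 1.08 for KRTAP2-3 and 1.06 for KRT34 on the log2 scale, and of -3.57 for C11orf96, -2.47 for AREG, -2.39 for BMF, -2.27 for CHI3L1 and -2.17 for IL24. CLDN1 had 1.39, a call lost without 1 kPa replicate 1 (adjusted p = 0.347), 1 kPa replicate 2 (0.254), plastic replicate 1 (0.116) or plastic replicate 2 (0.115), with RLE scaling (0.0608), with no filter (0.197) and in a fit of the gels alone (0.115). It was lost as well with correction of exon length (0.0627), GC (0.0729) or both (0.0789). The 10 kPa mean lay between those of 1 and 40 kPa for 943 of the 967 genes changed at least 2-fold between them, at a median of 36.5% of the change. Chance would also place an intermediate sample there often, since genes were selected for the difference of the outer groups. The slope count was 1141 without 1 kPa replicate 1, 1233 without 1 kPa replicate 2, 1281 without 40 kPa replicate 1, 1609 without 40 kPa replicate 2, 5591 without plastic replicate 1 and 5618 without plastic replicate 2.

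Plastic against the 40 kPa gel extends the range to a rigid dish, but changes the material as well. CCN1 stood at 670 ± 170 CPM on plastic and 660 ± 79.3 CPM on 40 kPa, and COL1A1 at 2634 ± 868 and 2870 ± 249 CPM (SD, n = 2). The genes with the smallest p were FAP, with a log2 fold change of 0.72, and IGFBP3, which binds insulin-like growth factors, with -0.89 (adjusted p = 0.0929 for each). TAGLN had 0.58 (adjusted p = 0.177), INHBA 0.48 (0.189), NRG1 -0.64 (0.152), the cell cycle inhibitor CDKN1A -0.77 (0.152) and GDF15 -0.92 (0.177). edgeR called 0 genes here, with 2400 at an unadjusted p under 0.05, and DESeq2 called 38 higher and 79 lower. The plastic libraries differed from each other more than any other pair, with a chi-square per degree of freedom of 89.3 over genes against 6.55 to 12.5 for the gels. A fit without 1 of them takes the spread of plastic from the gels, so its calls measure how 1 library departs and not an effect of plastic. Without plastic replicate 1 or plastic replicate 2 the log2 fold change was 0.89 and 0.53 for FAP, -1.01 and -0.78 for IGFBP3 and 0.45 and 0.50 for INHBA. Without plastic replicate 1 it was 0.63 for TAGLN, -0.69 for NRG1 and -0.96 for CDKN1A. IGFBP3 had -0.96 without 40 kPa replicate 2. COL1A1 stood at 3247 CPM in plastic replicate 1 and 2020 CPM in plastic replicate 2, so its log2 fold change was -0.51 without the former and 0.17 without the latter. DESeq2 called FAP, IGFBP3, CDKN1A, NRG1, TAGLN and INHBA (adjusted p of 1.06e-05 to 0.0101), and a fit of only the 2 groups compared IGFBP3 (0.0126) and GDF15 (0.0313). With no filter on low counts edgeR called these 6 and GDF15 (2.26e-07 to 0.0409). GC correction, chosen after the data were seen, gave calls for FAP (0.0428), IGFBP3 (0.0272) and NRG1 (0.0490), and correction of GC and exon length for the same 3 genes (0.0148, 0.00956 and 0.0470) and TAGLN (0.0204). The log2 fold change of COL1A1 was 0.05 and 0.15 under these 2 corrections, neither called.

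**Figure D5:**
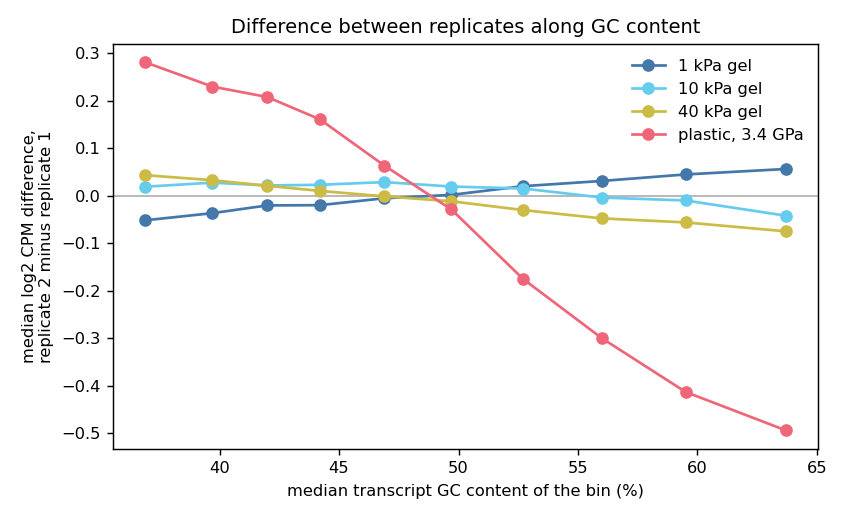
Points give the median log2 difference of replicate 2 over replicate 1 within each substrate, for 10 bins of genes of at least 10 CPM, against the GC content of their exons in percent. For plastic it goes from 0.28 at 36.9% GC to -0.49 at 63.7% GC.

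In the 8-library fit with the filter on low counts and no correction, edgeR called no member of a list between plastic and the 40 kPa gel, and the list tests gave several shifts. The S phase list was called higher (adjusted p = 3.87e-07; CCNE2 had 0.73 and RFC4 0.46, neither called) and the ribosomal protein list as well (adjusted p = 6.90e-14; RPL39 0.41, RPS24 0.38). The inflammatory (adjusted p = 7.09e-10), p53 target (2.03e-08; BTG2 -0.78) and immediate early lists (1.08e-08; DUSP5 -0.62, EGR1 -0.54) were called lower. None of these was called with an estimated correlation (adjusted p = 0.581 for each). The median of the ribosomal list was 0.25, and 0.05 without plastic replicate 2 (adjusted p = 0.00196); RPL39 stood at 232 CPM in plastic replicate 1, 330 CPM in plastic replicate 2 and 212 CPM on average on 40 kPa. Without plastic replicate 1 the log2 fold change was 0.64 for RPL39 and 0.60 for RPS24, with plastic replicate 2 as the only plastic library. The S phase list was not called without 40 kPa replicate 2 (adjusted p = 0.134). In the inflammatory list CXCL8 had -2.18, IL6 -1.34 and CSF3 -1.94, and 27 of its 30 genes were higher in 40 kPa replicate 1 than in 40 kPa replicate 2. Without 40 kPa replicate 1 the inflammatory list was not called (adjusted p = 0.474). The YAP/TAZ list (adjusted p = 0.00961), the cholesterol (0.0250) and ATF4 lists (0.00272) were called lower and the mitochondrially encoded genes higher (0.00818), none with an estimated correlation (adjusted p = 0.581, 0.581, 0.476 and 0.581). Without 40 kPa replicate 1 the YAP/TAZ and mitochondrial lists were not called (adjusted p = 0.0793 for each), nor were they without plastic replicate 2 (0.764 and 0.858). The cholesterol and ATF4 lists were not called without 40 kPa replicate 2 (0.169 and 0.0802) or plastic replicate 1 (0.127 for each). Without plastic replicate 1 the log2 fold change was 0.61 for RFC4, 0.92 for CCNE2, -0.99 for BTG2 and -0.85 for DUSP5. DUSP5 had -0.43 without plastic replicate 2. Without 40 kPa replicate 2 the value was -2.19 for IL6 and -2.56 for CSF3. DESeq2 called CCNE2, DUSP5 and BTG2 with all libraries (adjusted p of 0.00606 to 0.0152). With no filter edgeR called these 3, CSF3 and EGR1 (3.19e-09 to 0.0221), and with correction of GC and exon length DUSP5 (0.0248). A fit that keeps 1 plastic library takes its spread from the gels, so its count measures how that library departs from them. The count of changed genes was 6201 without plastic replicate 1, 35 without plastic replicate 2, 36 without 40 kPa replicate 2 and 1 without 40 kPa replicate 1.

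Leaving out a library brought calls for 9 lists that were not called with all 8, and for 4 of them the direction turned with the plastic library kept. Without plastic replicate 1 the collagens (adjusted p = 0.000495; 1 rose and 19 fell), the TGF-beta list (0.00536; 4 and 15), the matrix glycoproteins (0.0386; 5 and 13) and the focal adhesion genes (0.0410; 4 and 9) were called lower, none with an estimated correlation (adjusted p of 0.455 or more). Without plastic replicate 2 the same 4 lists were called higher (2.02e-07, 0.00184, 0.00766 and 0.0110), with 1, 2, 0 and 0 members that rose and 0 that fell, and none with an estimated correlation (adjusted p = 0.356 for each). The actin and contractile genes (0.000359) and proteases (0.00823) were then called higher as well, and the G2/M (2.38e-09), histone (0.00626) and growth factor lists (0.0382) lower, again none with an estimated correlation (adjusted p of 0.356 to 0.416). Without 40 kPa replicate 1 the histone (0.00335) and growth factor lists (0.0416) were called lower, but not with an estimated correlation (adjusted p = 0.585 for each). With all 8 libraries the adjusted p of these 9 lists was 0.0726 or more.

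Plastic was last set against the 1 kPa gel, with 2098 genes higher and 2609 lower, 242 and 898 at least 2-fold. In a fit of only the 2 groups compared the count was 3008. KRTAP1-5 rose by 2.33, EDN1 (endothelin 1) by 1.94, the adhesion scaffold NEDD9 by 1.94 and CD274 by 1.86 on the log2 scale. ANKRD1 went from 21.8 to 87.2 CPM, a call lost without plastic replicate 2 (adjusted p = 0.0604). C11orf96 fell by 7.30, CYP1A1 by 4.19, BMF by 4.07, AREG by 3.98 and PDK4 by 3.65. Of 22 YAP/TAZ targets 13 rose and 1 fell (14 and 2 adjusted over the list alone; adjusted p = 1.19e-07, and 0.309 with an estimated correlation), and of 34 S phase genes 27 rose and 0 fell (29 and 0; adjusted p = 1.31e-14, and 0.309 with an estimated correlation). The YAP/TAZ rises were 8 without 1 kPa replicate 1. The count was 2171 without 1 kPa replicate 1, 1975 without 1 kPa replicate 2 and 8412 without plastic replicate 1.

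Comparisons that share no library were set beside each other. The log2 fold changes of 40 against 1 kPa and of plastic against 10 kPa had a Pearson r of 0.577 across 17128 genes, which are not independent replicates, and 2573 of the 2747 genes called in the former (93.7%) had the same sign in the latter; with no filter on low counts r was 0.0937. For 10 against 1 kPa and plastic against 40 kPa, r was 0.011, and 23 of 55 called genes (41.8%) had the same sign.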

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

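The test for an outlying library needs 4 or more libraries per group and was not applicable here. A signal outside the gene counts was seen in 40 kPa replicate 2: 38.6% of its records were not uniquely aligned, against at most 19.9% in any other library. Its 44602509 gene counts were within the range of the rest.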

How the results depend on the processing

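The corrections along gene properties and their values below were chosen after the data were seen. So was leaving out a library together with an estimated correlation. The other settings given here were planned. The largest shifts of the counts came with fits that used fewer groups or fewer libraries. With a fit of only the groups compared, calls were 1452 for 10 against 1 kPa and 6100 for 40 against 1 kPa. They were 2172 for 40 against 10 kPa, 17 for plastic against 40 kPa and 3008 for plastic against 1 kPa. The slope over the gels had 5635. Among the gels such a fit drops the plastic pair, which adds to the shared estimate of the spread in the main fit. Leaving out either plastic library raised the gel counts as well, so these rises go with the plastic pair. What else moved the counts was not tested. Leaving out each library gave 0 to 1142, 1241 to 5745, 197 to 2645, 0 to 6201, 1975 to 8412 and 1141 to 5618 calls in the same order. Where a group then keeps 1 library, that library is assumed to vary like the other groups. The plastic pair varied more than any gel pair, so counts that rest on 1 plastic library measure how that library departs. For 10 against 1 kPa, library size alone gave 17 calls, no filter 243, the filter of 50 counts 29 and DESeq2 165. For plastic against 40 kPa, no filter gave 203 and DESeq2 117. GC correction gave 136 calls for 10 against 1 kPa, 1334 for 40 against 10 kPa and 15 for plastic against 40 kPa. Correction of GC and exon length together gave 226 for 10 against 1 kPa, 4257 for 40 against 1 kPa, 1773 for 40 against 10 kPa, 39 for plastic against 40 kPa and 4068 for the slope. The cause of these shifts was not tested beyond the weighing of the plastic libraries in the closing observations.

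With the replicate number as a block, plastic against 40 kPa gave 1 call, and 6 genes named for 10 against 1 kPa lost theirs; it ended no other named call, and other counts stayed within 1.5 times. Same-numbered libraries did not deviate together (correlations from -0.0325 to 0.0581), and the labels do not say that a number marks a shared culture. With an estimated correlation camera called 0 lists in each comparison, against 16, 12, 10, 9, 15 and 12 with the preset one in the order above; leaving out a library gave 10 to 16 lists for 10 against 1 kPa and 6 to 16 for plastic against 40 kPa, and 0 in each comparison with an estimated correlation, a combination added after the data were seen. Without a filter, r between 40 against 1 kPa and plastic against 10 kPa was 0.0937. Of 168 pairs of a named gene and a comparison, 138 were called; 89 of these stayed called in the same direction under every setting and 49 lost the call under at least 1. Of the uncalled pairs, 24 were called under at least 1 setting. A reversal was counted only where the gene was called in the main fit or under the setting. By that count 0 pairs reversed, while in 17 results a value called in neither changed sign. RLE scaling and shrinkage without the robust option kept every count of changed genes within 1.5 times.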

Other observations

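The 3 corrections along gene properties, the marker sums per library and the search for shared exon bases were chosen after the patterns had been seen; only the bounds for the joint correction were set before its fit was run. Between the 40 and 1 kPa gels, of 27 interferon-stimulated genes, 1 rose and 6 fell (1 and 6 adjusted over the list alone), with STAT2 falling by 0.81 and IRF1 by 0.79 on the log2 scale (adjusted p = 0.0219, and 0.457 with an estimated correlation; 0.161 without 40 kPa replicate 2 and 0.0502 without plastic replicate 1). With any of the 1 or 40 kPa libraries left out 0 of them rose. Of 20 p53 targets 0 rose and 2 fell (0 and 2 adjusted over the list alone): GDF15 by 1.64 and TP53INP1 by 1.22 (adjusted p = 0.0211, and 0.625 with an estimated correlation; 0.171 without 40 kPa replicate 1). Neither gene was called in a fit of only the 2 groups compared (adjusted p = 0.0925 and 0.0809), and the falls in the list were 6 without plastic replicate 1 or plastic replicate 2. HMGCS1, of the mevalonate pathway, fell by 0.71 among 25 cholesterol genes (0 rose and 2 fell, likewise 0 and 2 adjusted over the list alone; adjusted p = 0.183); the list had 0 rises and 11 falls without plastic replicate 1, 1 and 11 without plastic replicate 2, and 0 and 1 without 1 kPa replicate 1, 1 kPa replicate 2 or 40 kPa replicate 1. DDIT4 fell by 1.36 among 30 ATF4 and unfolded protein response genes (2 rose and 1 fell, likewise 2 and 1 adjusted over the list alone; adjusted p = 0.909; 6 and 6 without plastic replicate 1 or plastic replicate 2). The rises in it were 1 without 10 kPa replicate 1 or 10 kPa replicate 2, and 0 with any of the 1 or 40 kPa libraries left out.

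Of 16 fatty acid synthesis genes 0 rose and 2 fell, of 29 glycolysis and hypoxia genes 1 rose and 2 fell, of 13 mitochondrially encoded genes 1 rose and 0 fell, and of 69 ribosomal protein genes 0 rose and 0 fell in edgeR's test. Adjusted over the list alone these counts were 0 and 4, 1 and 1, 0 and 0, and 0 and 0, and camera called none of these lists (adjusted p = 0.464, 0.894, 0.879 and 0.394). Without plastic replicate 1 the fatty acid list had 2 rises and 7 falls, and without plastic replicate 2 it had 2 and 6. Without either of these libraries 4 glycolysis genes rose and 6 fell, and 1 mitochondrial gene rose and 3 fell. The fatty acid falls were 1 without 1 kPa replicate 1 or 40 kPa replicate 1 and 0 without 1 kPa replicate 2. With any of the 1 or 40 kPa libraries left out 0 glycolysis genes rose; 0 fell without 40 kPa replicate 1, and 1 fell with any other gel library left out. Of the mitochondrial genes 1 rose without 40 kPa replicate 1, and 0 rose with any other gel library left out. Replication-dependent histone genes, whose RNA mostly lacks a poly(A) tail, had 5 rises and 0 falls of 24, or 6 and 0 adjusted over the list alone (adjusted p = 0.00416, and 0.478 with an estimated correlation; 0.0829 without 40 kPa replicate 2). The rises among them were 0 without 1 kPa replicate 1 or 1 kPa replicate 2, 2 without 40 kPa replicate 1 and 1 without 40 kPa replicate 2. Of these H2AC6 had 0.52 and H2BC12 0.41, and both calls were lost without 1 kPa replicate 1 (adjusted p = 0.123 and 0.170), 1 kPa replicate 2 (0.0835 and 0.204), 40 kPa replicate 1 (0.102 and 0.192) or 40 kPa replicate 2 (0.0636 and 0.126), and that of H2BC12 also without 10 kPa replicate 1 (0.0542) or 10 kPa replicate 2 (0.0543). The glucose transporter genes SLC2A1 and SLC2A3 had 0.56 and -0.64; the call of SLC2A1 was lost without 1 kPa replicate 1 (0.0686), 1 kPa replicate 2 (0.123), 40 kPa replicate 1 (0.0673) or 40 kPa replicate 2 (0.101), and that of SLC2A3 without 40 kPa replicate 1 (0.0542). KRT7, a keratin among the epithelial markers (2 of 8 tested rose, 2 fell), rose by 1.11; KRT8 had -0.62, a call lost without 1 kPa replicate 2 (adjusted p = 0.280) or 40 kPa replicate 1 (0.290). NOTCH3, a pericyte marker (4 of 11 rose, 3 fell), fell by 1.86. Of the fibroblast markers 3 of 20 rose and 7 fell; of the endothelial 2 of 10 rose and 6 fell; of the leukocyte 0 of 6 rose and 2 fell. Adjusted over the list alone the counts were 2 and 3 for the epithelial, 5 and 3 for the pericyte, 4 and 10 for the fibroblast, 2 and 7 for the endothelial and 0 and 2 for the leukocyte markers; camera called none of these lists (adjusted p = 0.464, 0.450, 0.0636, 0.122 and 0.0557). Without 1 kPa replicate 1, 1 kPa replicate 2, 40 kPa replicate 1 and 40 kPa replicate 2, the falls were 4, 6, 3 and 6 for the fibroblast, 2, 2, 2 and 3 for the endothelial, 1, 0, 0 and 2 for the epithelial, 1, 2, 1 and 2 for the pericyte and 2, 1, 0 and 1 for the leukocyte markers. The rises were 0 in each for the fibroblast markers, 2, 4, 3 and 4 for the pericyte, 2, 2, 1 and 2 for the endothelial and 2, 2, 1 and 2 for the epithelial. Without plastic replicate 1 or plastic replicate 2, 12 fibroblast markers fell; 3 epithelial markers rose and 3 fell, and 1 fell without 10 kPa replicate 1 or 10 kPa replicate 2. The fibroblast list was called lower without plastic replicate 1 (0.00453) or plastic replicate 2 (0.00550), and the leukocyte list without 1 kPa replicate 1 (0.0421), 10 kPa replicate 1 (0.0375) or 10 kPa replicate 2 (0.0371). With an estimated correlation neither list was called in these cases (adjusted p = 0.212 and 0.251 for the fibroblast list, and 0.474, 0.478 and 0.478 for the leukocyte list). After correction of GC, alone or with exon length, KRT8 was not called (0.0539 and 0.0530), nor was H2BC12 after that of exon length (0.0809).

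The plastic libraries differed from each other along GC content. In the main fit edgeR called no gene between plastic and the 40 kPa gel. DESeq2 did call genes there, as did edgeR with no filter on low counts. In genes of at least 10 CPM the median log2 difference of replicate 2 minus replicate 1 went from 0.28 at 36.9% GC to -0.49 at 63.7% GC (Spearman rho -0.66 across 9133 genes, which are not independent; -0.32 to 0.35 within the gel pairs). Along exon length the largest trend was within the 10 kPa pair (rho 0.436). It was -0.215 within plastic, 0.107 within 40 kPa and -0.0249 within 1 kPa. For plastic against 40 kPa, correction along exon length left 0 calls. That cannot decide, since 0 calls would also follow if the substrates differed little. The correction left the SD of the log2 difference within the plastic pair at 0.327, from 0.333 without correction. These SDs argue against exon length alone as the source of the spread of that pair. The corrections of GC (15 calls) and of both (39 calls) fell between 0 calls, the bound against a cause, and 100, the bound for one, so GC cannot be told apart from another difference between the plastic libraries. After both corrections the SD of the log2 difference was 0.209 for plastic, down from 0.333, against at most 0.146 for the gels; a bias of library preparation may account for part of the spread, and a difference between the dishes stays open.

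Several chemokine and NF-kB target genes were highest in 40 kPa replicate 1; CXCL8 (66.3 against 23.1 CPM) and IL6 (7.52 against 3.25 CPM) were also higher in 10 kPa replicate 1 than in 10 kPa replicate 2, but lower in replicate 1 than in replicate 2 on 1 kPa (24.1 against 29.2 and 3.43 against 4.64 CPM) and on plastic (20.5 against 34.5 and 4.51 against 6.01 CPM). Of 30 genes of the inflammatory list, 17 were over 2-fold higher there than in 40 kPa replicate 2 and 0 over 2-fold lower (median log2 difference 1.35). CXCL1 (51.5 against 5.59 CPM), CXCL5 (258 against 53.3 CPM) and ICAM1 (26.1 against 3.69 CPM) were picked after their values were seen. The 16 leukocyte markers with a mean under 1 CPM summed to 1.07 CPM in 40 kPa replicate 1. Their sum was 0.905 CPM in 40 kPa replicate 2 and up to 1.91 CPM elsewhere. Some of these markers were lower on 40 kPa than on 1 kPa (LAPTM5 0.074 against 0.522 CPM, CD74 0.342 against 0.616 CPM). The highest other library is therefore a poor bar, and the low sum argues only against a large share of leukocytes. PTPRC, TYROBP and HLA-DRA were at 0 CPM in both 40 kPa libraries, whereas LYZ (0.0757 CPM) and CD163 (0.133 CPM) had their highest means on 40 kPa. The sum over all 19 markers (6.58 CPM) decides nothing, as CORO1A alone averaged 3.70 CPM on 40 kPa. The sum of 18 epithelial markers with a mean under 1 CPM was 0.363 CPM in 40 kPa replicate 1. It was 0.181 CPM in 40 kPa replicate 2 and up to 0.590 CPM elsewhere. The sum in 40 kPa replicate 1 stayed below the highest other library, which argues against a large share of epithelial cells. Sums this low cannot exclude a small share. KRT19, whose mean was over 1 CPM and so outside the sum, averaged 2.08 CPM on 40 kPa against 0.814 to 1.10 CPM on the other substrates. A response of the fibroblasts themselves may remain and was not tested, as no label separates the replicates.

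NUSAP1 and PRC1, both needed in mitosis, and ASNS, asparagine synthetase, had means of 0.304, 0.913 and 0.366 CPM, although the medians of their lists were 103 and 76.6 CPM. A candidate explanation is that HTSeq set aside reads shared with an overlapping gene model on the same strand. In GENCODE 29, 62.2%, 57.6% and 44.6% of their exon bases are shared in this way. All 3 near-zero genes of these lists (100%) share at least 40%, against 0 of the 91 others and 5.24% of all protein-coding genes; the limit of 40% was set after those 3 shares were seen, and at a limit of 90% none of the 3 would pass. The rest of their exon bases is unshared in GENCODE 29, and whether such an overlap could bring counts this near 0 was not tested. The authors' annotation is not known, so the levels of these 3 genes are uncertain.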
